A study of Schizosaccharomyces pombe with 16 samples.

How the data were processed

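The series measured polyadenylated RNA of the fission yeast Schizosaccharomyces pombe on biotin-labelled Affymetrix arrays, per the labels' protocols. The wild-type strain was L972 and the mutant carried fcp1-452, a temperature-sensitive allele of fcp1, the gene of the phosphatase that acts on the carboxy-terminal domain of RNA polymerase II. Cultures were in a synthetic minimal medium with nitrogen (+N) or in the same medium without it (-N), at 26 or 37 °C. The 16 arrays came in a pair of sets: set 1 held 1 array of each of the 8 groups of strain, nitrogen and temperature, and set 2 held replicates 1 and 2 of the 4 groups with nitrogen. Groups were taken from the sample titles and source names, because the longer sample description repeats a single condition for every array. The time spent at 37 °C or without nitrogen is not given in the sources used here.

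The deposited values were linear ratios of 4999 probe sets on each array. Robust multi-array averaging (RMA) is named in the submitters' processing notes, with no version. The values showed a later step: within each set, every probe set had a median of 1 over the 8 arrays. Each value was thus a ratio to the probe set's own median in that set. The lowest value was 0.01, reached by 4 of 79984 values. No expression level was therefore kept, and differences between arrays were interpretable within a probe set only. The number of arrays limited the precision, and signal over background was not known from ratios. Gene names came from the platform annotation given with the series, updated through the RefSeq gene table of assembly ASM294v3, which was used for names only. A single gene was given for 2917 probe sets, several genes for 20, and 2062 probe sets were not in that annotation and stayed unnamed here. Of the annotated identifiers, 2914 were found in the RefSeq table, 110 names were updated, and 14 genes had several probe sets. No genome was used and no coordinates are given.

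Replicates were compared before any averaging. In each of the 4 groups with nitrogen, the set 1 array and the set 2 replicate 1 array were nearly identical once each set was centred: r = 0.975 to 0.990 across probe sets, against 0.652 to 0.765 between the set 1 array and replicate 2. The SD of their log2 difference was 0.0572 to 0.0742, against 0.214 to 0.381 for replicate 2. The small difference between the strains at 26 °C recurred between set 1 and set 2 replicate 1 (r = 0.887) and not between set 1 and replicate 2 (r = -0.00369). The differences lay far under the spread between replicates, so the 2 arrays of each such pair were averaged and counted as 1 sample. Set 1 was first put on the scale of set 2 by each probe set's mean difference over the 4 pairs, and the same shift was applied to the -N arrays. This left 12 samples: 2 in each group with nitrogen and 1 in each group without. Nothing in the labels says that replicates came from separate cultures, so p-values measured the spread between these samples, which may be technical.

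Log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior 2.75 degrees of freedom and prior SD 0.135) with a mean for each of the 8 groups and the replicate number as a block, which left 3 residual degrees of freedom. The design written before the data were examined had the set as a term over 16 arrays. With each duplicate counted once, the samples of set 1 are exactly those of replicate 1, so the set term becomes the replicate block. The pairing check was made before calls were compared: the difference between replicates 1 and 2 correlated between every 2 of the 4 groups, with r across probe sets from 0.636 to 0.863 over the 6 pairs of groups. The fit of 16 arrays with the set term and the fit without the block are given beside the results they move. Contrasts were tested with Benjamini-Hochberg adjustment over 4999 probe sets and called at an adjusted p under 0.05, with the count at 2-fold or more beside it. The 9 tested comparisons were the temperature effect in each strain with nitrogen, the strain effect at each temperature with nitrogen, the interaction of strain and temperature, nitrogen starvation averaged over the 4 conditions, the interaction of strain and nitrogen, and the strain and temperature effects without nitrogen. Tests that involve -N arrays took the spread from the groups with nitrogen, and so assumed that the single -N arrays vary alike. Another 6 comparisons of single arrays of set 1 were counted at 2-fold or more. Their counts of calls in the same fit, with the spread borrowed from the groups with nitrogen, are given beside them.

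The gene lists, 25 in number, and the rule for named genes were fixed with that design. The lists covered heat shock proteins, the induced environmental stress response, mating and Ste11-dependent genes, markers of P cells, nitrogen source uptake, autophagy and vacuolar proteolysis, ribosomal proteins, ribosome biogenesis with RNA polymerase I, glycolysis with hexose transport, mitochondrial respiration, the tricarboxylic acid cycle, G1/S and DNA replication, mitosis with septation, core histones, RNA polymerase II factors, phosphate uptake, amino acid biosynthesis, purine and pyrimidine biosynthesis, iron and copper uptake, the proteasome, genes named for induction in meiosis (meu and mug), meiotic recombination with sporulation, secretion with lipid synthesis, the spliceosome, and tRNA synthetases. Lists were tested with camera (preset correlation 0.01, Benjamini-Hochberg over the lists), with camera using an estimated correlation, and with fry. No list call held with an estimated correlation in any of the 9 comparisons. That version rested on 3 residual degrees of freedom, so a call was hard to reach at any correlation. In the mutant's temperature effect with nitrogen, the estimate was -0.098 for core histones and 0.0081 for G1/S and DNA replication, both under the preset. Their unadjusted camera p still went from 2.41e-04 to 0.031 and from 9.62e-05 to 0.027. A lost call thus cannot by itself be put down to correlation between members. Members were counted as called over all probe sets and adjusted over the list alone. For single arrays, a list's median was placed among 10000 random lists of the same size, unmatched on level because the ratios hold none. Random lists do not keep the correlation between members of a list, so percentiles can be extreme for small medians. The named genes were fcp1 in every comparison, the 10 largest rises and 10 largest falls among named probe sets at an adjusted p under 0.05 and at least 2-fold that moved the same way in every replicate or condition, and up to 4 members of each called list with the smallest adjusted p. For single arrays they were the 10 largest differences in each direction among probe sets whose higher value lay above that array's median. A gene with several probe sets was named by the one with the highest mean.

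Alternatives were the 16 arrays as deposited with a set term, without one and with a replicate block of 3 levels, no replicate block, quantile normalization, median centring, a trended and robust prior, array weights, one probe set per gene, subsets of the arrays, a 2-fold threshold and each sample left out in turn. Without a -N sample, an average over temperatures or strains was taken over the conditions left. An offset of 0.05 before the logarithm, the omission of the wild-type samples of replicate 2 and, for the 3 comparisons averaged over a pair of conditions, the omission of -N samples were added after the data had been seen. Left out were the planned filter on probe sets of low mean and the planned offset of 16, since ratios centred near 1 carry no level, and any check of gene length, since only 2914 of 4999 probe sets could have one. The calculation was tested on simulated data of 4999 probe sets: for the temperature effect in fcp1-452 it recovered 23.9% of 1.5-fold, 88.1% of 2-fold and 100% of 4-fold changes with 5 false calls, and for the interaction of strain and temperature 4.48%, 58.2% and 95.5% with 8 false calls. For nitrogen starvation it recovered 86.6%, 95.5% and 100% with 21 false calls, and for the temperature effect in wild type 38.8%, 85.1% and 100% with 3. The 21 false calls stood beside 58, 64 and 66 recovered probe sets, a larger share than the threshold of 0.05 names. Simulated noise was independent between probe sets and equal in every group, -N included, and few probe sets were changed. The simulation thus does not test the assumption of equal spread. Figures were drawn with matplotlib 3.10.9.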

Results

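The study profiled messenger RNA of fission yeast in wild type and in the temperature-sensitive mutant fcp1-452, grown with nitrogen or starved of it, at 26 °C (permissive) and 37 °C (restrictive). Its title names the genetic control of cellular quiescence, the resting state that this yeast enters when nitrogen runs out. After the duplicate arrays were merged there were 2 samples in each of the 4 groups with nitrogen and 1 in each of the 4 groups without, each a set of 4999 probe set ratios. Changes are given as log2 differences ± SE from limma, n = 2 per group with nitrogen and n = 1 without, and adjusted p-values are limma's with Benjamini-Hochberg adjustment. All -N samples are of replicate 1. With the replicate block, the change on starvation averaged over the 4 conditions is therefore set against replicate 1 with nitrogen alone. Replicate 2 adds only to the spread there. The plot of called probe sets by comparison shows how unevenly the changes fell over the design.

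**Figure D1:**
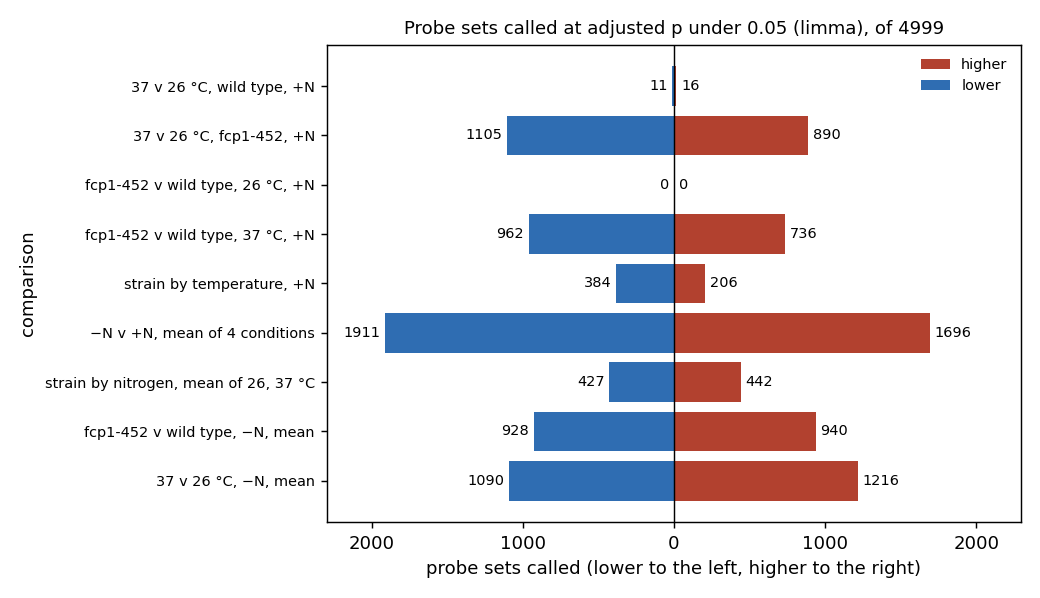
Probe sets called at an adjusted p under 0.05 in each of the 9 tested comparisons (horizontal axis, number of probe sets, lower to the left and higher to the right of 0). With nitrogen, 27 were called for temperature in wild type and 1995 in fcp1-452, and none for the strain at 26 °C.

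The first comparison asked what 37 °C did to wild-type cells with nitrogen. Of 4999 probe sets, 16 were higher and 11 lower, and 26 of them passed 2-fold. The named genes that rose were gal10, an enzyme of galactose use (2.79 ± 0.22, adjusted p = 0.0128), the protein kinase gene ppk31 (1.83 ± 0.17) and hri1, a kinase of translation initiation factor eIF2 (1.48 ± 0.11). The meiotically induced genes mug146 (1.81 ± 0.22), mug126 (1.21 ± 0.14) and mug133 (1.12 ± 0.13) rose too, as did dni2 (1.02 ± 0.10). Those that fell were the ferric reductase frp1 (-1.92 ± 0.10, adjusted p = 0.00636), the oligopeptide transporter isp4 (-1.54 ± 0.16), the stress-activated kinase srk1 (-1.40 ± 0.14) and the biotin transporter vht1 (-1.38 ± 0.10). The small heat shock protein gene hsp16 stood at 2.18 ± 0.69 and was not called (adjusted p = 0.167). The value for fcp1 itself was 0.00 ± 0.12 (adjusted p = 0.987).

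Among the gene lists in wild type, camera called 5 lower and 1 higher, each with few or no members past the threshold by themselves. Histone genes had a median of -0.35, with 0 of 11 called over all probe sets and 2 lower when adjusted over the list alone (adjusted p = 0.699 with an estimated correlation). The tricarboxylic acid cycle also had a median of -0.35, with 0 of 13 called and 4 lower when adjusted over the list alone. Amino acid biosynthesis (median -0.18, 44 genes) and ribosomal proteins (median -0.06, 119 genes) had 0 members called in either way, and so did mitochondrial respiration (median -0.15, 33 genes). Of the 134 meu and mug genes 3 rose, and 22 were higher and 2 lower when adjusted over the list alone. For these 5 lists the adjusted p was 0.765 with an estimated correlation, except for respiration, where it was 0.80. The effects of the 2 replicates correlated at r = 0.686 across probe sets, and 79 probe sets were at 2-fold or more the same way in both, where independent lists would share 3.04. The count of 27 became 296 for the 16 arrays with a set term, 385 after quantile normalization and 0 without the replicate block or without the wild-type samples of replicate 2. It was 3, 4, 8 and 605 without replicate 1, and 3, 1, 8 and 605 without replicate 2, of wild type at 26 °C, wild type at 37 °C, fcp1-452 at 26 °C and fcp1-452 at 37 °C in turn.

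The same temperature shift in fcp1-452 with nitrogen changed many more genes. Of 4999 probe sets 890 rose and 1105 fell, with 203 and 375 of them at 2-fold or more. The largest named rises were hsp16 (4.70 ± 0.69, adjusted p = 0.00535), mug108 (3.61 ± 0.32), say1 (3.28 ± 0.30), the metallothionein gene zym1 (3.01 ± 0.56) and the Hsp70 gene ssa1 (2.88 ± 0.62, adjusted p = 0.0159). The meiotic genes meu13 (2.60 ± 0.47), hop1 (2.35 ± 0.33) and mcp7 (2.12 ± 0.25), which act in the pairing and recombination of meiotic chromosomes, rose too. The largest named falls included the proline permease put4 (-4.47 ± 0.26, adjusted p = 0.000916), the replication licensing factor cdt1 (-4.05 ± 0.37), the amino acid transporter aat1 (-4.02 ± 0.23) and the ammonium transporter amt1 (-3.90 ± 0.23). The cell surface protein genes adg1 (-3.92 ± 0.41) and adg2 (-3.31 ± 0.27), isp7 (-3.60 ± 0.41), mmf2 (-3.58 ± 0.19) and frp1 (-3.41 ± 0.10, adjusted p = 0.000399) fell as well. The transcript of fcp1 did not pass the test (-0.24 ± 0.12, adjusted p = 0.157). The labels call the allele temperature-sensitive, which a transcript level does not check.

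Camera called 13 lists in the mutant, 4 higher and 9 lower. Amino acid biosynthesis fell in 29 of 44 genes and rose in none, the same when adjusted over the list alone, among them gcv1 of glycine cleavage (-2.70 ± 0.17), his2 (-1.54 ± 0.11), arg5 (-1.52 ± 0.12) and arg3 (-1.28 ± 0.11). Nitrogen source uptake fell in 9 of 27 and rose in 1, with the same counts adjusted over the list alone, led by put4, amt1, the glutamate synthase glt1 (-1.88 ± 0.14) and the glutamate dehydrogenase gdh1 (-1.74 ± 0.12). Iron and copper uptake fell in 10 of 20 and rose in 1 (11 and 1 adjusted over the list alone), including frp1, abc3 (-2.35 ± 0.16) and the zinc transporter zrt1 (-1.21 ± 0.11). Ribosomal protein genes fell in 28 of 119 and rose in none (18 adjusted over the list alone), with rpl1603 at -3.31 ± 0.34 and rps2601 at -0.85 ± 0.11. That share of falls was near that of all probe sets, 1105 of 4999. Autophagy and vacuolar proteolysis rose in 12 of 23 and fell in 1 (16 and 1 adjusted over the list alone), with atg17 at 1.38 ± 0.10, atg15 at 1.28 ± 0.12 and atg12 at 1.06 ± 0.12. Proteasome genes rose in 11 of 29 and fell in 1, with the same counts adjusted over the list alone, among them rpn11 (0.77 ± 0.13) and pup1 (0.74 ± 0.10). The meu and mug genes rose in 41 of 134 and fell in 17 (45 and 17 adjusted over the list alone). For these 7 lists the adjusted p was 0.418 with an estimated correlation.

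Genes of G1/S and DNA replication fell in 24 of 53 and rose in 3 (28 and 4 adjusted over the list alone): the large ribonucleotide reductase subunit cdc22 at -3.08 ± 0.22, the ubiquitin ligase adaptor cdt2 at -2.71 ± 0.22, the cyclin cig2 at -2.48 ± 0.18 and the replication protein A subunit ssb2 at -1.50 ± 0.13. Core histones fell in 8 of 11 (9, with 1 higher, adjusted over the list alone), with hht1 at -1.59 ± 0.10 and hta2 at -1.21 ± 0.13; for both lists the adjusted p was 0.386 with an estimated correlation. Purine and pyrimidine biosynthesis fell in 11 of 18, the same adjusted over the list alone, with ade5 at -2.12 ± 0.22. Secretion and lipid synthesis fell in 14 of 34 and rose in 1, the same adjusted over the list alone, and included the fatty acid synthase genes fas2 (-1.07 ± 0.10) and fas1 (-0.99 ± 0.10) and the acetyl-CoA carboxylase cut6 (-0.97 ± 0.11). Spliceosome genes rose in 14 of 72 and fell in 6 (12 and 5 adjusted over the list alone), with cwf24 at 1.21 ± 0.14 and prp3 at -1.35 ± 0.13. That share of rises was near that of all probe sets, 890 of 4999. For these 3 lists the adjusted p was 0.475 with an estimated correlation. The tRNA synthetases fell in 13 of 22 and rose in 1 (14 and 1 adjusted over the list alone; adjusted p = 0.474 with an estimated correlation). Replicate effects correlated at r = 0.777 across probe sets, and 392 probe sets were at 2-fold or more the same way in both, where independent lists would share 51.4. After quantile normalization 705 rose and 681 fell, so the excess of falls was not kept. The count of 1995 became 593 without the replicate block and 941 without the wild-type samples of replicate 2. It became 730 without fcp1-452 at 26 °C replicate 1 and 508 without its replicate 2.

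**Figure D2:**
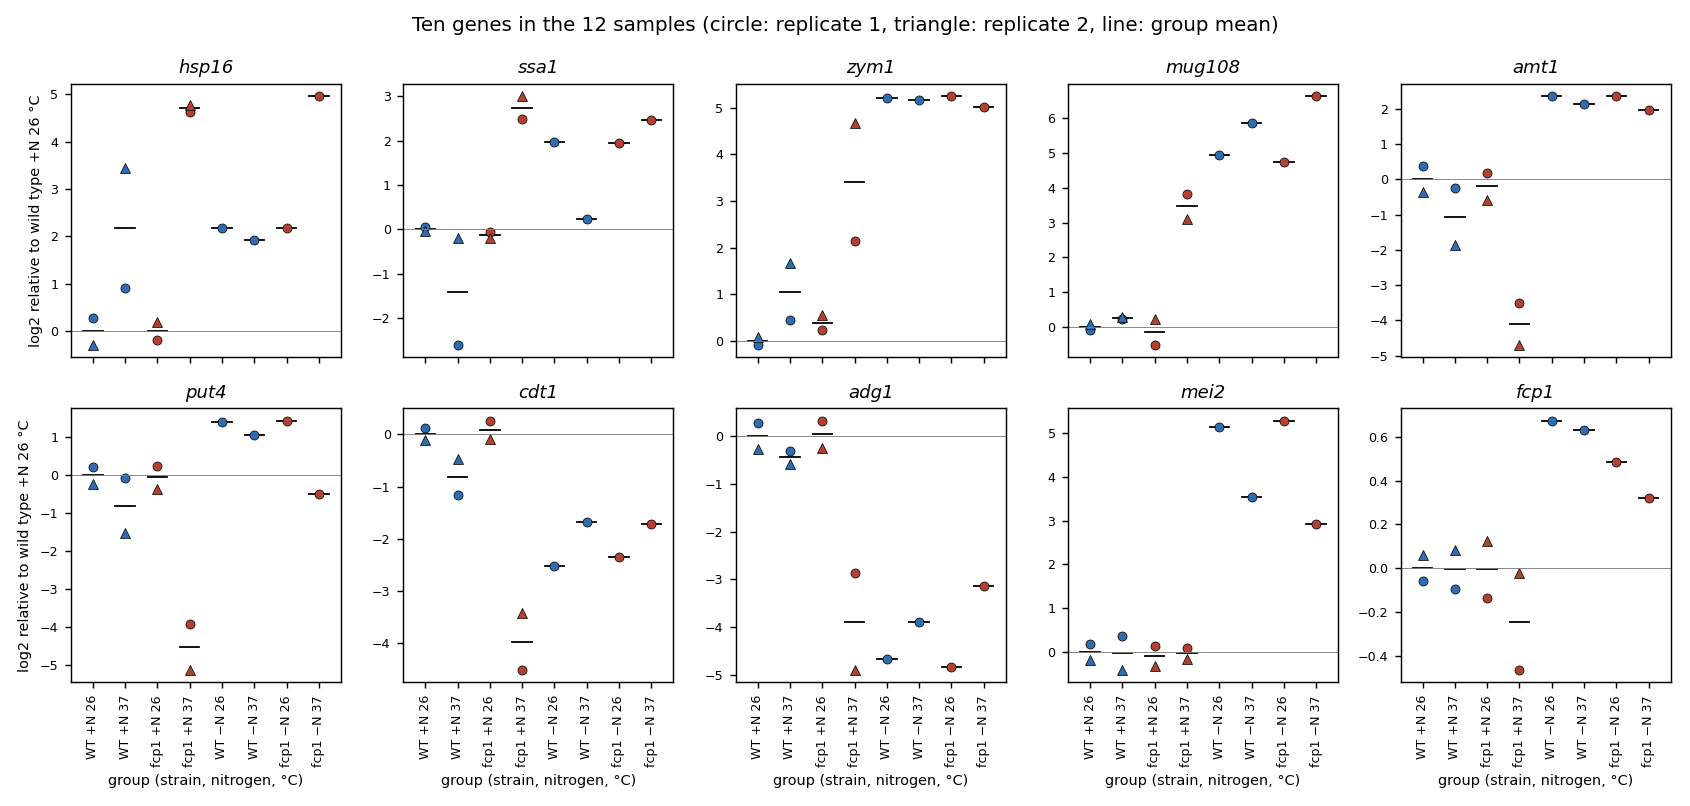
Values of 10 genes in the 12 samples (vertical axis, log2 relative to the mean of wild type with nitrogen at 26 °C; horizontal axis, the 8 groups of strain, nitrogen and temperature in °C). Circles are samples of set 1 and replicate 1, triangles replicate 2, and a line marks each group's mean, which without nitrogen is the single sample; hsp16 of wild type at 37 °C with nitrogen differed between replicates, at 0.91 and 3.45.

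At 26 °C with nitrogen, the strains were compared at the temperature the mutant tolerates. No probe set was called by limma, and 19 of 4999 had an unadjusted p under 0.05. The difference for fcp1 was 0.00 ± 0.12. The strain differences of the 2 replicates did not correlate across probe sets (r = -0.0111), with SDs of 0.181 and 0.185, and no probe set was at 2-fold or more the same way in both. Ribosomal protein genes were the only list that camera called, with a median of -0.02 and 0 of 119 called over all probe sets or adjusted over the list alone (adjusted p = 0.962 with an estimated correlation). Without the wild-type samples of replicate 2, 1 probe set was called, and it was lower in fcp1-452.

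At 37 °C with nitrogen the strains differed at 1698 probe sets, of which 736 were higher and 962 lower in fcp1-452, with 171 and 311 at 2-fold or more. The chaperone gene ssa1 was the largest named rise (4.15 ± 0.62, adjusted p = 0.0074), and hsp16 (2.52 ± 0.69, adjusted p = 0.0386), lsd90 (2.50 ± 0.49), zym1 (2.35 ± 0.56) and the trehalase gene ntp1 (2.30 ± 0.47) were higher as well. The DNA glycosylase gene mag1 was higher by a smaller and more precise amount (1.95 ± 0.12). The largest falls were aat1 (-4.13 ± 0.23, adjusted p = 0.00107), the galactokinase gal1 (-3.83 ± 0.28), put4 (-3.73 ± 0.26), mmf2 (-3.54 ± 0.19), adg1 (-3.44 ± 0.41), cdt1 (-3.15 ± 0.37) and amt1 (-3.04 ± 0.23). The value for fcp1 was -0.24 ± 0.12 (adjusted p = 0.169).

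Camera called 14 lists for this strain difference. Over all 4999 probe sets 736 were higher and 962 lower. The lower counts of ribosomal proteins and of secretion with lipid synthesis did not exceed that share. G1/S and DNA replication was lower in 24 of 53 and higher in 3 (29 and 3 adjusted over the list alone), and nitrogen source uptake was lower in 11 of 27 and higher in 1 (12 and 1 adjusted over the list alone). Histones were lower in 6 of 11 and higher in 1 (8 and 1 adjusted over the list alone), and the proteasome was higher in 15 of 29 and lower in 1, the same adjusted over the list alone. For these 4 lists the adjusted p was 0.471 to 0.472 with an estimated correlation. Examples were cdc22 (-2.64 ± 0.22), cig2 (-2.29 ± 0.18), glt1 (-1.95 ± 0.14), the histone H3 gene hht1 (-1.35 ± 0.10) and rpn11 (1.02 ± 0.13). Autophagy was higher in 12 of 23 and lower in 1 (15 and 1 adjusted over the list alone), with the kinase gene atg1 at 1.19 ± 0.13 and atg13 at 1.44 ± 0.14. Mitochondrial respiration was higher in 6 of 33 (3 adjusted over the list alone), amino acid biosynthesis lower in 21 of 44 (22 adjusted over the list alone) and ribosomal proteins lower in 22 of 119 (15 adjusted over the list alone). Lower as well were tRNA synthetases, in 10 of 22 with 1 higher (11 and 1 adjusted over the list alone), nucleotide biosynthesis, in 12 of 18 (the same), and secretion with lipid synthesis, in 6 of 34 with 1 higher (6 and 0). The spliceosome was higher in 14 of 72 and lower in 6 (13 and 6 adjusted over the list alone), and for the last 8 lists the adjusted p was 0.559 with an estimated correlation. Heat shock genes were higher in 5 of 19, the same adjusted over the list alone, with cdc37 at 1.02 ± 0.12 and mdj1 at 0.91 ± 0.10, and stress response genes were higher in 10 of 31 and lower in 4 (11 and 4 adjusted over the list alone). For this pair the adjusted p was 0.629 with an estimated correlation. The 1698 calls became 340 without the replicate block, 721 after quantile normalization (375 higher and 346 lower, so the balance turned) and 173 without the wild-type samples of replicate 2. They became 482 without wild type at 37 °C replicate 1 and 551 without its replicate 2.

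The interaction of strain and temperature tested directly whether the mutant's response to 37 °C differed from that of wild type with nitrogen. It was called for 590 probe sets, 206 with a higher and 384 with a lower response in fcp1-452, of which 92 and 232 differed 2-fold or more. The response was more positive in the mutant for ssa1 (4.29 ± 0.88, adjusted p = 0.0388), mug108 (3.35 ± 0.45), the trehalose-6-phosphate synthase tps1 (1.87 ± 0.42) and mag1 (1.80 ± 0.17). It was more negative for aat1 (-4.14 ± 0.32, adjusted p = 0.00745), put4 (-3.67 ± 0.37), gal1 (-3.61 ± 0.39), mmf2 (-3.60 ± 0.27), adg1 (-3.48 ± 0.59), cdt1 (-3.23 ± 0.52), the hexose transporter ght3 (-3.06 ± 0.38) and abc3 (-3.04 ± 0.23). Part of the value for ssa1 came from the wild-type sample of replicate 1 at 37 °C, at -2.61 against -0.20 in replicate 2. For fcp1 the interaction was -0.23 ± 0.17 (adjusted p = 0.385). The same 14 lists were called as for the strain difference at 37 °C, 6 more positive and 8 more negative, with adjusted p = 0.462 to 0.611 with an estimated correlation. G1/S and DNA replication had 13 of 53 members more negative (19 adjusted over the list alone) and none more positive, amino acid biosynthesis 12 of 44 (17 adjusted over the list alone), and autophagy 7 of 23 more positive (8 adjusted over the list alone). The count of 590 became 933 for the 16 arrays with a set term, 7 without the replicate block, and 19 both after quantile normalization and without the wild-type samples of replicate 2. It was 0, 39, 10 and 1717 without replicate 1, and 0, 53, 13 and 1220 without replicate 2, of wild type at 26 °C, wild type at 37 °C, fcp1-452 at 26 °C and fcp1-452 at 37 °C in turn.

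Nitrogen starvation, averaged over both strains and temperatures, gave the widest change of the 9 comparisons. Of 4999 probe sets 1696 rose and 1911 fell, with 639 and 672 at 2-fold or more, and 2774 of the 3607 had the same sign in all 4 conditions. Among the largest rises, not given in full, were the M-factor pheromone precursor genes mfm1 (5.08 ± 0.28, adjusted p = 5.05e-05) and mfm3 (3.97 ± 0.09). The uracil-regulated gene urg1 (4.73 ± 0.15), mug108 (4.68 ± 0.23), the alpha-galactosidase gene mel1 (4.45 ± 0.36) and the amino acid permease isp5 (4.28 ± 0.23) were others. Large rises were also seen for mei2, whose RNA-binding product starts meiosis (4.04 ± 0.10, adjusted p = 1.73e-05), and the pheromone pathway kinase spk1 (3.73 ± 0.44). The largest falls were the copper transporter ctr4 (-3.83 ± 0.32), adg1 (-3.48 ± 0.29), the sugar nucleotide transporter hut1 (-3.41 ± 0.08, adjusted p = 1.73e-05), the serine biosynthesis gene ser2 (-3.06 ± 0.13) and lsm8 (-2.96 ± 0.26). The RNA polymerase III subunit genes rpc17 (-2.96 ± 0.11) and rpc31 (-2.45 ± 0.07) and the ribosomal protein gene rpl1603 (-2.48 ± 0.24) fell too. With nitrogen, lsm8 was higher in replicate 1 than in replicate 2 by 3.01 on average over the 4 groups. That is as large as its fall, which was measured against replicate 1 alone. The transcript of fcp1 rose as well (0.72 ± 0.08, adjusted p = 0.000577), higher without nitrogen in 4 of 4 conditions.

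By gene list, starvation raised nitrogen source uptake in 21 of 27 genes and lowered 2, the same adjusted over the list alone (adjusted p = 0.658 with an estimated correlation), with isp4 at 2.72 ± 0.11, the GABA transaminase uga1 at 2.70 ± 0.08 and the uracil permease fur4 at 2.38 ± 0.08. Mating and Ste11-dependent genes rose in 20 of 24 and fell in 1, and autophagy rose in 19 of 23 and fell in none, both the same adjusted over the list alone. Examples of the latter were atg1 (2.36 ± 0.09), atg13 (1.97 ± 0.10) and the vacuolar sorting kinase vps15 (1.79 ± 0.10). Glycolysis and hexose transport rose in 9 of 21 (7 adjusted over the list alone), with the enolase eno102 at 3.02 ± 0.09 and the transporter ght7 at 2.94 ± 0.15. The tricarboxylic acid cycle rose in 8 of 13, the same adjusted over the list alone, with kgd2 at 0.97 ± 0.07. Stress response genes rose in 16 of 31 and fell in 5, the same adjusted over the list alone, including the cation ATPase cta3 (2.51 ± 0.07), the transcription factor gene atf1 (1.83 ± 0.12) and the mitochondrial thioredoxin trx2 (-1.44 ± 0.08). Ribosomal protein genes fell in 43 of 119 and rose in 1 (35 and 0 adjusted over the list alone). Over all probe sets 72.15% were called, 1911 of 4999 lower, so that share of falls was not larger. For these 6 lists the adjusted p was 0.862 with an estimated correlation. Lists that camera did not call in any of the 9 comparisons held changes in both directions here. Mitosis and septation rose in 21 and fell in 19 of 49 genes, and RNA polymerase II factors rose in 16 and fell in 27 of 55, both the same adjusted over the list alone. For mitosis and septation the median (-0.01) and mean (-0.10) lay below 0 while camera's direction was up. Meiotic recombination and sporulation rose in 20 and fell in 9 of 44 (19 and 9 adjusted over the list alone), and phosphate uptake rose in 4 and fell in 2 of 6, the same adjusted over the list alone. The single -N arrays were assumed to vary like the groups with nitrogen. In the 16 arrays without a set term 2383 probe sets were called, and in set 1 alone, 4 arrays against 4 with the condition as a block, 2058.

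**Figure D3:**
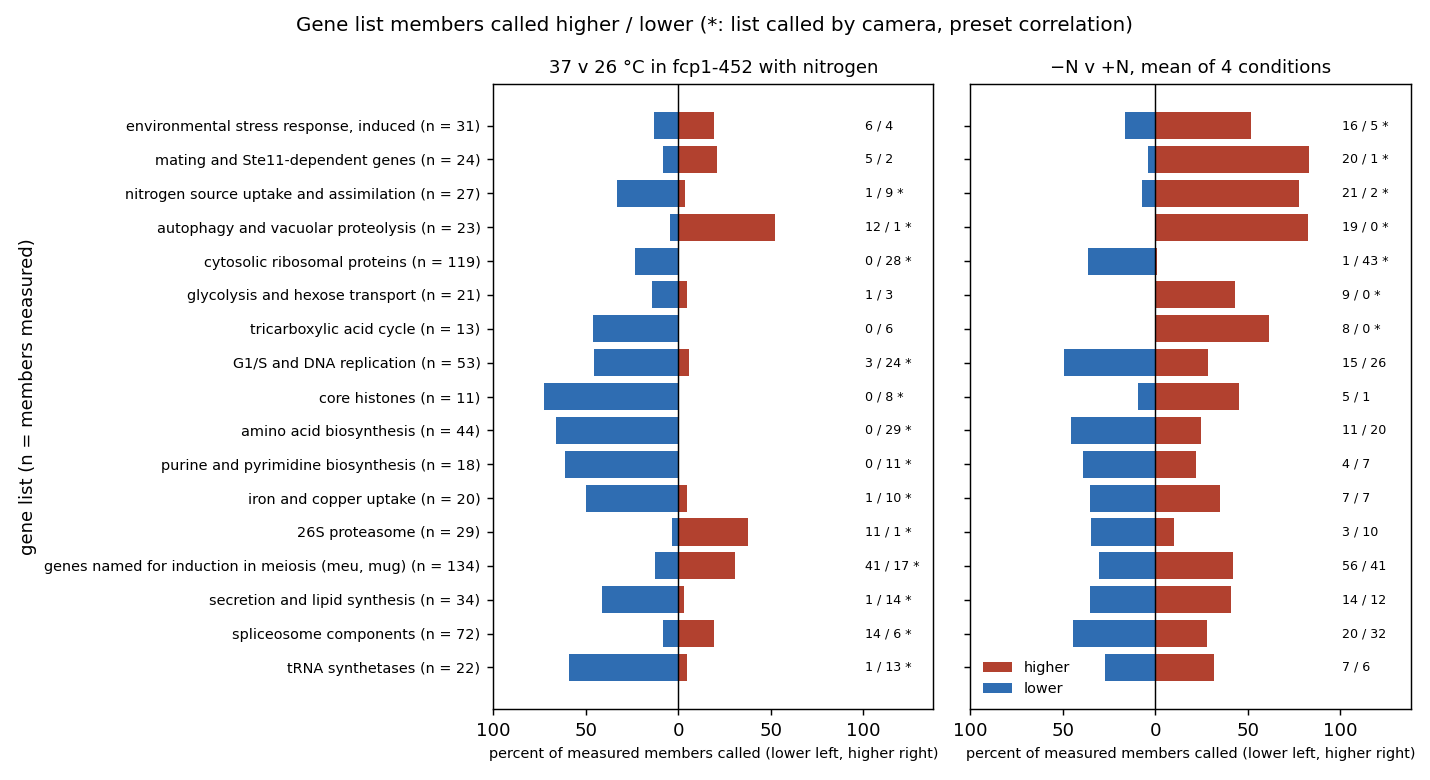
Percent of the measured members of 17 gene lists called higher or lower (horizontal axis, lower to the left) for the temperature shift in fcp1-452 with nitrogen and for nitrogen starvation; numbers give members higher and lower, and a star marks a list called by camera with a preset correlation. Autophagy genes rose in both panels (12 and 19 of 23), while nitrogen source uptake fell in 9 of 27 in the first and rose in 21 of 27 in the second.

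Nitrogen starvation in each strain at each temperature rested on single arrays of set 1, so the differences have no replicate check and are given without a p. With the spread borrowed from the groups with nitrogen, limma called 2515 and 2600 probe sets in wild type at 26 and 37 °C, and 2632 and 3180 in fcp1-452. In wild type at 26 °C, 630 probe sets were at least 2-fold higher and 713 at least 2-fold lower without nitrogen. The named rises were led by mfm1 (7.83), mfm3 (7.28), zym1 (5.32), urg1 (5.28), mel1 (5.19), mug108 (5.13) and mei2 (5.03). The named falls were led by adg1 (-4.92), frp1 (-4.89) and ctr4 (-4.47). In fcp1-452 at 26 °C the counts were 646 and 775, and the P-factor pheromone precursor gene map2 was highest (6.46), with mei2 at 5.15, the M-factor gene mfm1 at 4.69, adg1 at -5.14, ctr4 at -5.09 and frp1 at -5.02. In wild type at 37 °C the counts were 694 and 737, with ght7 at 5.93, eno102 at 5.55 and mfm1 at 5.10, and ser2 at -4.03. In fcp1-452 at 37 °C they were 1031 and 941, with mug14 at 7.61, urg2 at 6.99, ght3 at 5.69, isp5 at 5.64, amt1 at 5.48 and cta3 at 5.32, and hut1 at -3.87 and the thiamine-repressed gene nmt1 at -3.56. After quantile normalization the total for fcp1-452 at 37 °C became 864 in place of 1972. The array without nitrogen behind that total had the widest spread of all deposited arrays, with an SD of log2 ratios of 1.08.

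Autophagy genes had medians of 1.01 and 1.16 in wild type and 0.97 and 0.81 in fcp1-452 at 26 and 37 °C, and nitrogen source uptake 1.01, 1.14, 1.03 and 1.55, each at or above the 99.63 percentile of 10000 random lists. Mating genes had medians of 2.04 and 0.83 in wild type and 1.56 and 1.22 in fcp1-452. Histone genes differed most between these arrays: their median was -0.40 and 0.36 in wild type and -0.51 in fcp1-452 at 26 °C, and 1.77 in fcp1-452 at 37 °C, where 11 of 11 were at least 2-fold higher without nitrogen. That rise started from lower values with nitrogen, where the histone median for 37 against 26 °C in fcp1-452 was -1.21. Between the strains without nitrogen at 37 °C the histone median was 0.66. Both the 1.77 and the 0.66 rest on the single fcp1-452 array at 37 °C without nitrogen, the widest of all arrays.

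The strains were then compared without nitrogen, which asked whether the mutation changed the starved state. At 26 °C only 23 probe sets of the 2 single arrays differed 2-fold or more, 5 higher and 18 lower in fcp1-452, and 14 of them had a gene name. The M-cell genes were lower in fcp1-452: the pheromone precursors mfm2 (-6.52), mfm3 (-4.89) and mfm1 (-3.87), the P-factor receptor mam2 (-4.82), the M-factor exporter mam1 (-1.89) and mam4 (-1.58). The P-cell genes map2 (6.90) and map3, the M-factor receptor (2.23), were higher. Also beyond 2-fold were mag2 (-2.77), the mating-type switching gene swi2 (-1.47), dni2 (1.41) and isp3 (1.08). The P-cell list had a median of 2.23 over 3 genes, and the mating list -0.10 over 24. With nitrogen, mfm2 differed between the strains by -5.06 at 26 °C and -8.30 at 37 °C in replicate 1, and by -0.34 and -2.29 in replicate 2. At 37 °C the 2 single arrays differed at 1724 probe sets, 851 higher and 873 lower, and at 606 after quantile normalization, with mug9 at 4.92, mfm1 at -4.14, mcp3 at -4.10, mfm2 at -4.08 and mag2 at -4.03. The fcp1-452 array of this pair had 31.9% of probe sets at least 2-fold from their set median, more than any other array. That share was 12.9% for the wild-type array of the pair. Without nitrogen at 26 °C it was 9.56% in wild type and 10.6% in fcp1-452. List medians at 37 °C were 0.52 for the spliceosome, 0.49 for ribosome biogenesis and 0.67 for heat shock proteins, at the 99.99, 99.85 and 98.6 percentiles of random lists. On the lower side were mating genes (-0.63), amino acid biosynthesis (-0.44), nitrogen source uptake (-0.46) and nucleotide biosynthesis (-0.55), at the 1.01, 1.11, 3.59 and 3.66 percentiles. Such percentiles were also reached by small medians at 26 °C without nitrogen. Ribosomal proteins stood there at 0.05 (99.97 percentile) and meiotic recombination with sporulation at -0.11 (0 percentile). At 37 °C the values for all lists rest on 1 pair of arrays. The P-cell list had a median of -0.59 there (20.2 percentile), with map2 at 1.58, map3 at -0.59 and sxa1 at -0.65.

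**Figure D4:**
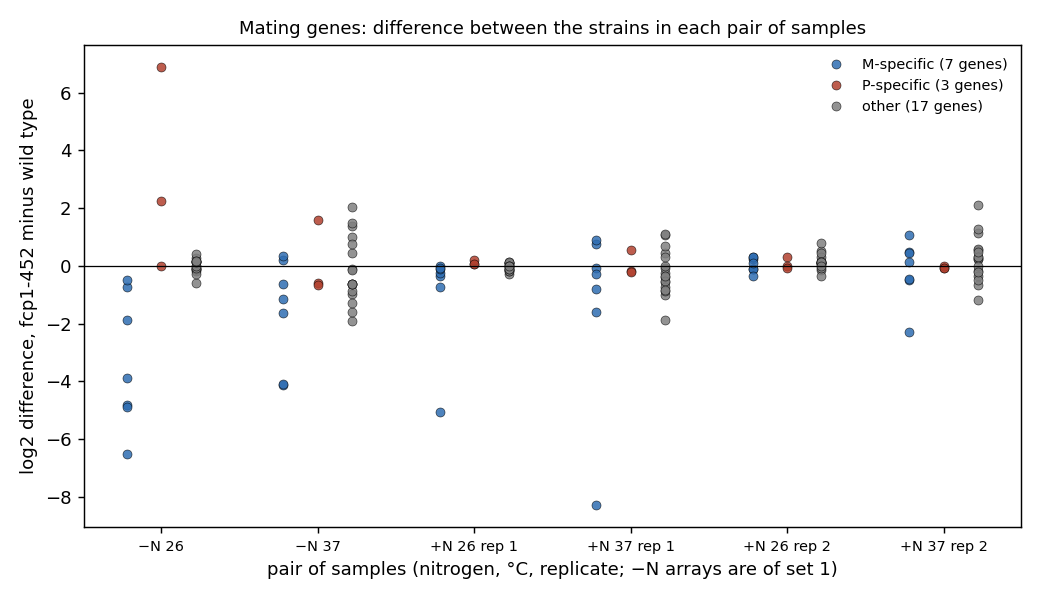
Difference between the strains (vertical axis, log2 fcp1-452 minus wild type) for 27 mating genes in the 6 pairs of samples (horizontal axis), with M-specific, P-specific and other mating genes apart. Without nitrogen at 26 °C the 7 M-specific genes had a median of -3.87 and the 3 P-specific genes 2.23, while the other 17 lay between -0.60 and 0.42.

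Averaged over temperatures, fcp1-452 without nitrogen differed from wild type at 1868 probe sets, 940 higher and 928 lower, with 182 and 236 at 2-fold or more. This average rested mainly on the single pair of arrays at 37 °C. In the same fit the strain was called for 2752 probe sets at 37 °C and 5 at 26 °C, and 1218 of the 1868 had the same sign at both. Without either -N sample of 1 temperature, the count is that of the other. The gene map2 rose most (4.24 ± 0.23, adjusted p = 0.00293), followed by rba50 (1.99 ± 0.19), mug89 (1.88 ± 0.15), cgs1, the regulatory subunit of protein kinase A (1.82 ± 0.12), and the transcription factor gene pcr1 (1.65 ± 0.17). Those that fell most were mfm2 (-5.30 ± 1.63), mfm1 (-4.01 ± 0.39), mfm3 (-3.27 ± 0.13), mam2 (-2.98 ± 0.16), mcp3 (-2.24 ± 0.26), swi2 (-1.80 ± 0.16) and the glutathione transferase gst2 (-1.78 ± 0.18). Camera called 3 lists, each with adjusted p = 0.918 with an estimated correlation. Spliceosome genes were higher in 26 of 72 and lower in 6 (31 and 6 adjusted over the list alone), with cwf2 at 1.29 ± 0.16. Ribosome biogenesis was higher in 15 of 56 and lower in 1, with the RNA polymerase I subunit rpa2 at 0.96 ± 0.13, and the proteasome was higher in 11 of 29 and lower in 1, the last pair the same adjusted over the list alone. At 26 °C alone the medians of these 3 lists were 0.03, 0.01 and 0.04, and at 37 °C alone 0.52, 0.49 and 0.44. For fcp1 the difference was -0.25 ± 0.12 (adjusted p = 0.147). The count of 1868 became 362 without the replicate block, 38 after quantile normalization and 718 without the wild-type samples of replicate 2. It became 2864 without fcp1-452 at 37 °C with nitrogen, replicate 1 or replicate 2.

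The interaction of strain and nitrogen tested whether the change from +N to -N differed in the mutant, averaged over temperatures. It can come from a strain difference with nitrogen as well as from one without it. It was called for 869 probe sets, 442 more positive and 427 more negative in fcp1-452, with 148 and 122 at 2-fold or more, and 582 of the 869 had the same sign at both temperatures. The genes map2 (4.03 ± 0.28, adjusted p = 0.0118), gal1 (1.95 ± 0.34), cdc22 (1.55 ± 0.27) and amt1 (1.54 ± 0.28) responded more positively. More negative were mfm3 (-3.81 ± 0.16, adjusted p = 0.00299), mfm1 (-3.43 ± 0.48), mam2 (-2.56 ± 0.20), mcp3 (-2.47 ± 0.32) and mug45 (-2.12 ± 0.24). At 37 °C without nitrogen amt1 stood at 1.96 in fcp1-452 and 2.13 in wild type. With nitrogen it stood at -3.49 and -4.70 in fcp1-452 and at -0.25 and -1.86 in wild type, so its interaction came from the values with nitrogen. The genes gal1 and cdc22 were lower in fcp1-452 at 37 °C with nitrogen as well. For fcp1 the interaction was -0.13 ± 0.14 (adjusted p = 0.559). Camera called ribosome biogenesis (8 of 56 more positive, the same adjusted over the list alone), histones (4 of 11, 7 adjusted over the list alone) and ribosomal proteins (1 of 119 more positive and 1 more negative, none adjusted over the list alone), with adjusted p = 0.754 with an estimated correlation for each. Examples were the RNA polymerase I subunit rpa34 (1.06 ± 0.16), the histone variant gene pht1 (1.25 ± 0.28) and hta1 (0.99 ± 0.13). The count of 869 became 1 without the replicate block and 0 both after quantile normalization and without the wild-type samples of replicate 2. It was 57, 136, 3 and 2117 without replicate 1, and 2, 133, 3 and 1766 without replicate 2, of the groups with nitrogen: wild type at 26 °C, wild type at 37 °C, fcp1-452 at 26 °C and fcp1-452 at 37 °C in turn. Without either -N sample at 37 °C, which leaves 26 °C alone, it was 5, and without either at 26 °C it was 1931.

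The last comparison set 37 °C against 26 °C without nitrogen, averaged over strains. Of 4999 probe sets 1216 were higher and 1090 lower at 37 °C, with 416 and 296 at 2-fold or more, and 1840 of the 2306 had the same sign in both strains. The largest rises were mug14 (4.51 ± 0.60), meu13 (4.42 ± 0.47), the hexose transporters ght7 (3.83 ± 0.21) and ght3 (3.44 ± 0.27), ppk31 (3.21 ± 0.17), hop1 (3.20 ± 0.33), aat1 (3.09 ± 0.23), gal10 (2.96 ± 0.22) and eno102 (2.89 ± 0.13). The falls were led by rgs1, a regulator of pheromone signalling (-3.00 ± 0.11, adjusted p = 0.000321), mfm1 (-2.27 ± 0.39), ste11, the transcription factor of the mating programme (-2.04 ± 0.15), mei2 (-1.99 ± 0.14), the pheromone pathway gene ste6 (-1.91 ± 0.19) and the mitotic phosphatase cdc25 (-1.88 ± 0.13). For fcp1 the value was -0.10 ± 0.12 (adjusted p = 0.505). Mating and Ste11-dependent genes fell in 12 of 24 and rose in 3, the spliceosome rose in 30 of 72 and fell in 7, and the meu and mug genes rose in 51 of 134 and fell in 19, each the same adjusted over the list alone (adjusted p = 0.921 with an estimated correlation). Histones rose in 9 of 11, with pht1 at 2.05 ± 0.23 and the centromeric cnp1 at 1.65 ± 0.22, and the P-cell markers fell in 3 of 3 averaged over strains, both the same adjusted over the list alone (adjusted p = 0.82 with an estimated correlation). The values for map2 and map3 were -4.71 and -2.71 in fcp1-452 but 0.61 and 0.11 in wild type, so only sxa1 was lower in both strains (-1.06 and -0.41). After median centring 1156 were higher and 1166 lower. The count of 2306 became 809 without the replicate block, 467 after quantile normalization and 1312 without the wild-type samples of replicate 2. It became 155 without either -N sample of fcp1-452, which leaves wild type alone.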

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

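Chosen only after the results were seen were the tests of mating type, of a weaker mating response, of exchanged labels, of the wild-type samples of replicate 2, of array-wide scaling at 37 °C without nitrogen and of the restrictive temperature. The test of scaling behind the replicate difference, the test of noise and the splits of the samples were written before.

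A pair of interactions passed the test of the difference between groups, but both counts depended on the fit. The response to 37 °C with nitrogen differed between the strains at 590 probe sets, led by aat1 (-4.14 ± 0.32) and ssa1 (4.29 ± 0.88). That count was 7 without the replicate block, 19 after quantile normalization and 0 without either replicate of wild type at 26 °C. The response to nitrogen starvation differed at 869, led by map2 (4.03 ± 0.28) and mfm3 (-3.81 ± 0.16), genes of opposite mating types. That count was 1 without the block, 0 after quantile normalization and 2 without replicate 2 of wild type at 26 °C with nitrogen. It was 5 at 26 °C alone and 1931 at 37 °C alone.

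The strains differed in mating-type genes without nitrogen at 26 °C, where 7 M-specific genes had a median difference of -3.87, 3 P-specific markers one of 2.23 and 17 other mating genes one of 0.01. A weaker mating response in the mutant cannot be judged from the P-specific median of 2.23. Starvation did not raise these markers in wild type at 26 °C (median -0.43), so a weaker response had little to lower in them. The 17 other mating genes had starvation medians of 1.78 in fcp1-452 and 1.66 in wild type at 26 °C. No weaker response was thus seen in that class, from single arrays. It stays open at 37 °C without nitrogen, where the P-specific median was -0.59 and that of the 24 mating genes -0.63. Exchanged labels of the 2 arrays without nitrogen at 26 °C are argued against because mfm2 was lower in fcp1-452 in the 3 other pairs of replicate 1 too, at -4.08 or below. A culture of P cells alone is argued against because 4 of the 7 M-specific genes were still 2-fold or more higher on starvation in fcp1-452 at 26 °C (median 1.48, mfm1 4.69), while the P-specific markers in wild type had a median of -0.43. A culture of fcp1-452 with cells of both mating types, mixed or switching, stays open and was not tested, as does the wild-type culture of replicate 2, where mfm2 differed by only -0.34 at 26 °C and -2.29 at 37 °C with nitrogen.

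Replicates 1 and 2 differed alike in the 4 groups with nitrogen, with 237 probe sets at least 2-fold higher in replicate 1 on average and 64 in replicate 2. On the higher side in replicate 1 were lsm8 (3.01), fhn1 (2.84) and swd3 (2.62), and on that of replicate 2 mug128 (-1.79) and meu7 (-1.61). Scaling of whole arrays would end the correlation between groups, yet its lowest value after quantile normalization was 0.702. The wild-type samples of replicate 2 alone would leave the 2 fcp1-452 groups uncorrelated, and r there was 0.691. A difference between days, cultures or array batches could remain, and no biological explanation was tested because the design names none.

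Without nitrogen at 37 °C the strains differed 2-fold or more at 1724 probe sets. Noise of the single arrays alone is argued against by r = 0.271 across probe sets with the strain difference at 37 °C with nitrogen in replicate 2. That pair shares no array with this one. Noise in much of the 1724 is not argued against. Of the 851 higher, 98 were 2-fold higher and 38 lower in replicate 2, where independent lists would share 44.9 and 70.5. Of the 873 lower, 167 were 2-fold lower and 23 higher there, where 72.3 and 46.1 would. Scaling alone is argued against by the 606 probe sets left after quantile normalization, although that is far under the count of 1724. Only 23 probe sets differed at 26 °C, which is consistent with an action of the mutation at the restrictive temperature, as a hypothesis, and a difference between these 2 cultures, with no replicate, stays open.

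For nitrogen starvation, 1 of 100 splits of the 12 samples into 4 and 8 gave as many probe sets as the real one, and that was the real split itself. It called 1997 in a fit of 2 groups with the replicate block. The highest of the other splits gave 46 and set 4 samples from 37 °C apart. The other splits leave the nitrogen difference in the residual, which lowers their counts. All -N samples are also single and of replicate 1, so the splits could not exclude chance.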

How the results depend on the processing

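The merging of duplicates with the replicate block, and the tests without the block, with an offset of 0.05, without the wild-type samples of replicate 2 and, for 869, 1868 and 2306, without each -N sample were chosen only after the data were seen. Over the called named genes, 8634 values under the alternatives held 7211 with the same call, 1403 that lost it and 20 that changed sign. Median centring, the offset, single-array controls taken from the fit of all samples, set 2 alone and the samples with nitrogen alone moved no count by more than 1.5 times, and the last of these is the same fit by construction. Comparisons are named here by their counts: temperature with nitrogen in wild type (27) and fcp1-452 (1995), strain at 26 °C (0) and 37 °C (1698), their interaction (590), nitrogen (3607), its interaction with strain (869), and strain (1868) and temperature (2306) without nitrogen.

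The replicate block paired the samples, and without it the counts were 0 for 27, 593 for 1995, 340 for 1698, 7 for 590, 1 for 869, 362 for 1868 and 809 for 2306, since the difference between replicates then enters the residual; the counts of 0 and 3607 moved by less than 1.5 times. A replicate block of 3 levels over the 16 deposited arrays counts duplicates as separate arrays and gave 1270 for 27, 3081 for 1995, 2958 for 1698, 2115 for 590 and 2070 for 869. With the set term, 16 arrays gave 296 for 27 and 933 for 590, and without it 48, 1073, 866, 237, 2383, 249, 713 and 1114 in the order above, leaving out the strain at 26 °C. Quantile normalization, which gives every array the same spread of ratios, led to 385 for 27, 721 for 1698, 19 for 590, 0 for 869, 38 for 1868 and 467 for 2306. Array weights gave 659 for 27, 1149 for 1995, 534 for 1698, 383 for 590, 1582 for 869 and 3011 for 1868, and a trended and robust prior 76 for 27; the cause was not tested. One probe set per gene tests fewer probe sets and gave 12, 1183, 973, 339, 2073, 538, 1110 and 1352, again without the strain at 26 °C. A threshold of 2-fold added to the adjusted p left 578 of 1995, 482 of 1698, 324 of 590, 1311 of 3607, 270 of 869, 418 of 1868 and 712 of 2306. Without the wild-type samples of replicate 2, which leaves fewer samples, counts were 0 for 27, 941 for 1995, 1 for 0, 173 for 1698, 19 for 590, 0 for 869, 718 for 1868 and 1312 for 2306. Set 1 alone gave 2058 for 3607.

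With each sample left out in turn the ranges were 1 to 605 for 27, 508 to 2657 for 1995, 0 to 0 for the strain at 26 °C, 482 to 2423 for 1698, 0 to 1717 for 590, 3109 to 4035 for 3607, 2 to 2117 for 869, 5 to 2864 for 1868 and 155 to 3202 for 2306. Without a -N sample the last 3 rested on the condition left, and the 20 changes of sign arose there, 2 for each gene and count below. At 26 and 37 °C alone these were naa38 (-0.0602 and 3.17), rpl44 (0.0770 and -1.30) and hta2 (-0.0609 and 1.37) for 869. For 1868 they were bms1 (-0.0203 and 1.77), rpn11 (-0.25 and 2.37), prp45 (-0.0219 and 1.99) and sme1 (-0.16 and 2.50). For 2306, in wild type and fcp1-452 alone, they were map3 (0.11 and -2.71), map2 (0.61 and -4.71) and sme1 (-0.0182 and 2.64). A group left with 1 sample was assumed to vary like the others, and the highest counts came without a sample of fcp1-452 at 37 °C with nitrogen, except for the strain at 26 °C. The replicates of that group differed most of the 4 groups with nitrogen (SD 0.383), and leaving 1 out takes that difference from the residual. Of the gene lists, camera with an estimated correlation, on 3 residual degrees of freedom, called 0 in all 9 comparisons. In total fry called 1 for 27, 0 for the strain at 26 °C and 19 for 3607. Of the lists called by camera with the preset, fry called 12 of 13 the same way for 1995. This was 10 of 14 for 1698, 8 of 14 for 590 and 7 of 7 for 3607. It was 1 of 3 for 869, 2 of 3 for 1868, 5 of 5 for 2306 and 1 of 6 for 27. A list is tested by fry by itself and not against the other probe sets. Of the single-array counts, quantile normalization moved those of fcp1-452 at 37 °C to 864 for starvation and 606 against wild type without nitrogen. The planned filter on low values and offset of 16 were not run, since the ratios hold no level, and signal over background is not known from them.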

Other observations

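All tests of this part, and the genes named in it, were chosen only after the results were seen. Wild-type nitrogen starvation at 26 °C and the shift of fcp1-452 to 37 °C with nitrogen were set side by side in arrays that share no sample, replicate 1 (merged with its duplicates) for the first and replicate 2 for the second. At 2-fold or more, 268 probe sets moved the same way in both, where independent lists would share 110.1, and 87 moved opposite ways, where 106.7 would. Across probe sets r was 0.283, and r between the same starvation values and the shift of wild type to 37 °C in replicate 2 was 0.169. For that shift of wild type, 56 probe sets moved the same way in both, where 26.6 would, and 46 opposite ways, where 28.0 would. Higher in both were zym1 (5.29 and 4.10), lsd90 (3.76 and 2.92), mug108 (5.02 and 2.88) and the chaperone genes ssa1 (1.93 and 3.21) and hsp16 (1.90 and 4.59). Lower in both were the surface protein genes adg1 (-4.93 and -4.66) and adg2 (-3.66 and -3.61), the ferric reductase frp1 (-4.85 and -3.41), aat1 (-2.97 and -4.29) and cdt1 (-2.64 and -3.33). By list, autophagy had 6 of 23 genes higher in both and 1 opposite, G1/S and DNA replication 8 of 53 lower in both and 0 opposite, and mitosis with septation 7 of 49 lower in both and 1 opposite. The count of 268 is the overlap itself and so does not test whether a part of the 2 responses is shared. Neither that nor slower growth in both conditions was tested.

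Of the 27 genes of nitrogen source uptake, 6 were higher in starvation and lower in the mutant at 37 °C, among them amt1 (1.99 and -4.11), isp7 (2.39 and -3.89), isp5 (3.97 and -2.13) and isp4 (2.45 and -1.85), and 2 were higher in both. Iron and copper uptake instead had 4 of 20 genes lower in both and none opposite, among them str3 (-2.57 and -5.41), and phosphate uptake 1 of 6 lower in both. Outside these lists, values were higher in starvation and lower in the mutant for mmf2 (2.63 and -3.45) and dak2 (2.83 and -2.48). The values for put4 in the mutant went from -3.92 and -5.13 in the 2 samples at 37 °C with nitrogen to -0.48 without it, relative to wild type with nitrogen at 26 °C. Those for amt1 went from -3.49 and -4.70 to 1.96.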
